A study of Mus musculus with 2 samples.

How the data were processed

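MicroRNA sequencing was done on heart tissue of 4-day-old female B6CASTF1/J mice, with RNA below 30 nt selected per the labels. The series has 2 libraries, each technical replicate 1 of its heart. Per the labels, replicate 1 came from the animal numbered 3 and replicate 2 from the animal numbered 4. Samples were grouped by the biological replicate number and tissue given in the labels, which makes 1 group.

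The deposited values are raw counts per microRNA gene, 1 file per library, with no normalization and no pooling of replicates. The deposited descriptions name the mm10 build and GENCODE M21 as the annotation. The aligner, the counting program, the adapter trimming and their settings are not given in the sources used here. Each file has 3 columns of counts, for both strands together, for the gene's own strand and for the opposite strand, and 4 summary entries in place of genes. That layout and the whole-number values are those of STAR's gene counting, which is an inference from the files and not a statement of the authors. All 2202 gene identifiers matched the M21 annotation, from which symbols, coordinates (1-based, mm10) and the surrounding genes were taken.

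The own-strand column was used, by a rule that took the stranded column with the larger total. It held 84.0% of the stranded counts in replicate 1 and 82.8% in replicate 2 (mean 83.4% ± 0.850, SD, n = 2). The column without strand leaves reads over genes on opposite strands unassigned (1223777 and 1177754 reads), which removes Mir378a and Mir126a, so it served only as an alternative. The summary entries stayed out of library sizes and tests. Of 14450527 reads in replicate 1, 44.4% were assigned to microRNA genes, 39.6% were multi-mapped, 11.9% were unmapped and 4.12% fell outside microRNA genes. Of 13495259 reads in replicate 2, these shares were 42.0%, 43.2%, 11.4% and 3.38%. The mean multi-mapped share was 41.4% ± 2.57 (SD, n = 2). Because multi-mapped reads are in no gene's count, a microRNA made from several identical copies is undercounted.

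To mark such genes, hairpin sequences were compared with each other on both strands. Of the 2202 genes, 1087 shared a stretch of 20 nt with another microRNA gene that did not overlap them. Overlapping genes were left out of each other's comparison, so stretches shared by opposite-strand partners such as Mir486 and Mir3107 were not marked. Of those 1087, 7.18% had at least 10 counts in each library, against 26.5% of the 1115 others. The sharing genes held 21.9% of the counts in replicate 1 and 20.7% in replicate 2. Sequence elsewhere in the genome was not searched, the counts are per hairpin gene and not per mature strand, and variants of the CAST parent against the reference were not examined. Gene lists were matched by symbol, which left a few members without a match.

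CPM was computed on the total own-strand count of a library. A gene was called detected with at least 10 counts in each library. Between the libraries, each gene with at least 10 counts in the sum was tested with a two-sided exact conditional binomial test on library sizes scaled by TMM factors (1.12 and 0.891, edgeR 4.0.16 in R 4.3.3), with Benjamini-Hochberg adjustment. A gene was called at an adjusted p under 0.05 and a fold over 2, with 0.5 added to each count in the log2 ratio of replicate 1 over replicate 2. This test compares 2 libraries and never conditions, and its noise is counting noise alone. The biological coefficient of variation is the square root of edgeR's common dispersion over detected genes. A chi-square statistic of 709 per degree of freedom over 491 genes showed that the libraries differed by more than the sampling noise, so they are not 1 library deposited again. It does not tell separate animals from repeat preparations of the same RNA. The libraries were counted as separate replicates because the labels name different animals.

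Shares of counts carry exact Clopper-Pearson 95% intervals, and pairs of genes were compared with Fisher's exact test adjusted over 12 pairs. The level of a list was also placed among 10000 random lists of the same size. No molecular identifiers are named in the labels, so reads are not independent molecules, and all intervals, standard errors of counting and floors cover counting error only. Statistics used Python 3.11.15, scipy 1.17.1, pandas 2.3.3 and numpy 2.4.6, and the plots used matplotlib 3.10.9.

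The test was tested on simulated libraries with 490 genes tested, whose counts held counting noise and no further spread between libraries. It called 42 of 50 genes simulated with a 3-fold difference, 47 of 50 at 5-fold, 49 of 49 at 10-fold and 4 of 50 at 1.5-fold, and 2 of 291 unchanged genes. These rates do not carry over to the real libraries, which differed by more than counting noise.

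Before the data were examined, the own-strand rule, the tests, the thresholds, 11 gene lists, 9 lists of cell type markers, 12 pairs and most alternatives were fixed. The rule for named genes took the 25 most abundant, all members of the muscle list, the 4 highest members of every other list, all pairs, and up to 5 genes per direction with the highest folds between the libraries and a mean of at least 100 CPM. Only 4 genes qualified as higher in replicate 1. The genes Mir205, Mir137, Mir223, Mir27b, Mir16-1, Mir18, Mir380, Mir496a, Mir539 and Mir668, and the genes of further clusters, were named after their values were seen. Alternatives included DESeq2 1.42.0 size factors, total-count scaling, other count minimums, the column without strand, other pseudocounts, edgeR's exact test with a dispersion estimated from both libraries as 1 group, and each library left out. That dispersion comes from the gap between the same 2 libraries that the test compares, so the test only sets each gene against their average gap. The deposited text descriptions hold no measurements and were used only for the build and the annotation.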

Results

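MicroRNAs were sequenced from the hearts of female mice of the hybrid strain B6CASTF1/J at 4 days after birth, a stage at which heart muscle is still maturing. The series held 2 libraries, 1 per heart, named biological replicates 1 and 2 in the labels, and both belonged to the same group. The labels named a different animal for each heart and gave both the same donor entry. No treated, older, male or other-tissue group was analysed here, so the data answered 2 questions, namely which microRNA genes were abundant in these hearts and how far the libraries of the 2 hearts differed from each other. Replicate 1 held 6417302 counts over microRNA genes and replicate 2 held 5662222. A floor of 3 counts corresponded to 0.467 CPM, counts scaled to a library's total, in replicate 1 and 0.530 CPM in replicate 2.

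By counts, which leave out multi-mapped reads, the most abundant gene was Mir378a (ENSMUSG00000105200.1). A microRNA made from several copies could rank above the genes named here, because its multi-mapped reads are in no gene's count. Mir378a lies in an intron of Ppargc1b, the gene of a transcriptional coactivator of mitochondrial metabolism (mm10, chromosome 18, 61397835 to 61397900, minus strand). It held 105623 ± 2965 CPM (SD, n = 2). Mirlet7i followed with 93958 ± 597 CPM (chromosome 10, 122985640 to 122985724, minus strand), and Mirlet7g, in an intron of Wdr82, held 79144 ± 2385 CPM (chromosome 9, 106178840 to 106178927, plus strand). Mir126a, an endothelial microRNA gene that overlaps an exon of Egfl7 (chromosome 2, 26591357 to 26591429, plus strand), held 62420 ± 14977 CPM, and the smooth muscle gene Mir143 held 52205 ± 9209 CPM. Mir378a lay above Mirlet7i in both libraries, and Mirlet7g lay above Mir126a in both, although the gap in replicate 2 was smaller (80830 against 73011 CPM).

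Of the 2202 microRNA genes annotated, 373 had at least 10 counts in each library, 71 reached 1000 CPM in each, and 1415 had 0 counts in both. The 10 most abundant genes held 55.48% of the counts in replicate 1 (95% Clopper-Pearson interval 55.44 to 55.52) and 57.90% in replicate 2 (57.86 to 57.94), a mean of 56.7% ± 1.71 (SD, n = 2). The top 25 held 79.2% ± 1.63 and the top 50 held 91.8% ± 0.700. After the first 5, the ranking continued with Mir23b (41012 ± 2059 CPM), Mirlet7d (37891 ± 5988 CPM), Mir99a (34763 ± 2590 CPM), Mir335 in an intron of the imprinted gene Mest (31843 ± 982 CPM) and Mir23a (28059 ± 8564 CPM). Places 11 to 25 were taken by Mir322, Mir26b, Mir351, Mirlet7b, Mir652, Mir139, Mir30d, Mir22, Mir99b, Mir21a, Mirlet7e, Mir30a, Mir30e, Mir151 and Mir130a, from 26636 CPM for Mir322 down to 8479 CPM for Mir130a. Mir378a, Mir23b and Mir23a share a stretch of 20 nt with another annotated microRNA gene, so reads that match both copies are not in these values. When all multi-mapped reads, whether or not from microRNA genes, were added to the total and none to the top 10, their share was 28.9%, a lower bound.

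**Figure D1:**
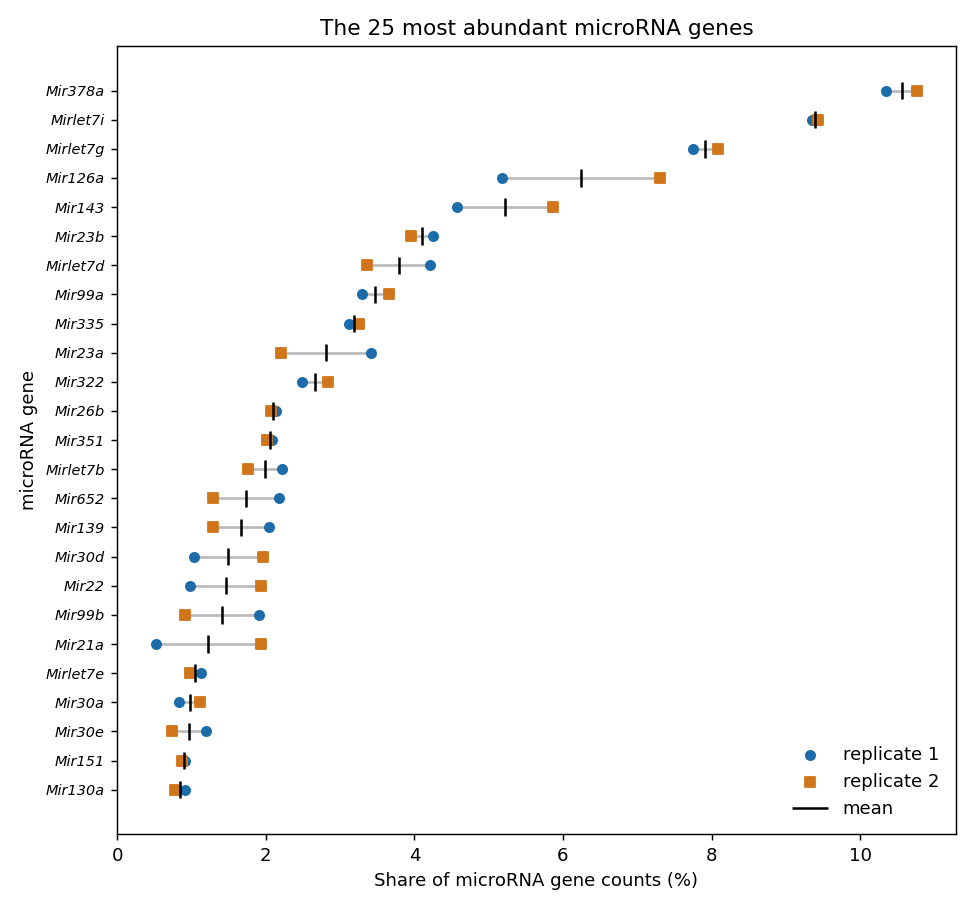
Share of all microRNA gene counts, in percent, held by each of the 25 most abundant microRNA genes in replicate 1 (circles) and replicate 2 (squares) of the 4-day-old female hearts, with the mean as a vertical line. Mir378a is highest at 10.6% on average, and the shares of Mir21a have the largest ratio between the libraries (log2 ratio −1.88, replicate 1 over replicate 2, or −2.21 after TMM scaling).

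Among the muscle microRNA genes, those lying inside myosin heavy chain genes held the most counts, with multi-mapped reads left out. Mir208a, in an intron of Myh6, the alpha cardiac myosin gene (ENSMUSG00000065432.1; chromosome 14, 54949060 to 54949142, minus strand), held 8451 ± 3439 CPM (SD, n = 2). Mir208b, in an intron of Myh7, the beta cardiac myosin gene (chromosome 14, 54975700 to 54975776, minus strand), held 6549 ± 1284 CPM. Mir499, in an intron of Myh7b (chromosome 2, 155622880 to 155622958, plus strand), held 5070 ± 3418 CPM. Mir206, known from skeletal muscle (chromosome 1, 20679010 to 20679082, plus strand), held 388 ± 466 CPM, from 4607 counts in replicate 1 and 331 in replicate 2.

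Of the 9 muscle genes, 3 differed by over 2-fold between the libraries in the exact binomial test, and the same number did when adjusted over the list alone. Mir206 was higher in replicate 1 (log2 ratio 3.28, counting SE 0.08, 9.74-fold), while Mir499 (−1.83, counting SE 0.01) and Mir1a-1 (−1.55, counting SE 0.58, 9 and 19 counts) were higher in replicate 2. With a dispersion estimated from the same libraries, edgeR's exact test gave an adjusted p of 0.0055 for Mir206 and 0.549 for Mir499. A call in that test marks a gene that stands out from the average gap between these libraries, and a gene not called may still differ. Counts were few for the copies of miR-1 and miR-133, microRNAs known as abundant in heart muscle: 136 and 190 for Mir1a-2, 36 and 43 for Mir133a-1, 12 and 2 for Mir133a-2, 10 and 9 for Mir133b. All 5 Mir1a and Mir133 genes share a stretch of 20 nt with another annotated microRNA gene, and reads matching several places were not counted for any gene, so these counts do not measure how much of either microRNA the hearts held. The whole muscle list held 2.05% ± 0.176 of the counts (SD, n = 2).

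**Figure D2:**
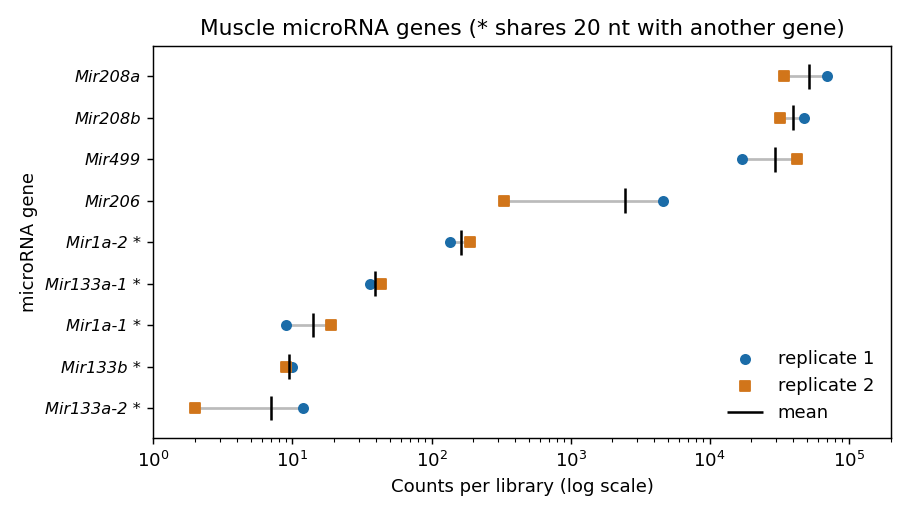
Counts per library, on a log scale, of the 9 genes of the muscle list in replicate 1 (circles) and replicate 2 (squares), with the mean as a vertical line and an asterisk on genes that share a 20-nt stretch with another gene. Mir208a, Mir208b and Mir499 lie at 17027 counts or more in both libraries, and the 5 genes with an asterisk lie at 190 counts or fewer.

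The let-7 family, microRNAs associated with differentiation, held 25.1% ± 0.627 of all counts (SD, n = 2), the largest share of the 20 lists examined. Its leading members were Mirlet7i (9.40% ± 0.0597), Mirlet7g (7.91% ± 0.239), Mirlet7d (3.79% ± 0.599) and Mirlet7b (1.99% ± 0.320), and none of the 12 measured members differed by over 2-fold between the libraries. Of those 12, 6 share a 20-nt stretch with another gene, but none of the leading members named does. The family's share and the order of its members cover only reads that were not multi-mapped. The miR-30 family held 3.53% ± 0.514, led by Mir30d (14961 ± 6584 CPM), Mir30a (9750 ± 1966 CPM) and Mir30e (9647 ± 3286 CPM). The next member, Mir30c-2, held 382 ± 81.0 CPM and shares a 20-nt stretch with another gene. Mir30d was the 1 member of 6 that differed, higher in replicate 2 (log2 ratio −1.26). The miR-15/16 family held 3.26% ± 0.286, of which Mir322 on the X chromosome made up the most (26636 ± 2466 CPM), ahead of Mir15b (2387 ± 362 CPM), Mir15a (1374 ± 590 CPM) and Mir195a (875 ± 541 CPM). Mir16-1 and Mir16-2 of this family share a 20-nt stretch with another gene, so multi-mapped reads are missing from their counts. The miR-17-92 cluster and its paralogs, known from proliferating cells, held 1.83% ± 0.333, with Mir17 at 5636 ± 1093 CPM, Mir93 at 5272 ± 1362 CPM, Mir92-1 at 2889 ± 711 CPM and Mir20a at 1935 ± 152 CPM. Of its 15 measured genes, 4 share a 20-nt stretch with another gene, Mir92-1 among them. The miR-29 family, known for targeting collagen transcripts, held 0.0247% ± 0.00120. Its highest member, Mir29a, held 200 ± 5.88 CPM, and Mir29c held 36.5 ± 18.8 CPM, Mir29b-1 8.70 ± 1.81 CPM and Mir29b-2 1.86 ± 0.867 CPM. Those last 3 share 20-nt stretches with another gene. Of the tested members, Mir195a (−1.68) and Mir16-1 (−1.19) of the miR-15/16 family, Mir18 (−1.08) of the miR-17-92 list and Mir29c (−1.43) were higher in replicate 2. Scaling by total counts brought Mir30d (−0.93), Mir16-1 (−0.85) and Mir18 (−0.75) inside 2-fold.

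MicroRNA genes of the imprinted Dlk1-Dio3 region on chromosome 12, which are expressed from the maternal chromosome, were broadly present. Of the 46 measured, 44 had at least 10 counts in each library, and together they held 2.39% ± 0.30 of the counts (SD, n = 2). The highest were Mir127 (5225 ± 2133 CPM), Mir379 (3326 ± 1318 CPM), Mir411 (3195 ± 149 CPM) and Mir541 (2005 ± 530 CPM). Of the 46 genes, 5 share a 20-nt stretch with another gene, Mir411 among them. Between the libraries 1 was higher in replicate 1, 4 were higher in replicate 2 and 39 did not pass. The 5 were Mir539 (log2 ratio 1.48), Mir380 (−1.73), Mir668 (−1.35), Mir379 (−1.16) and Mir496a (−1.01), of which Mir379 (−0.83) and Mir496a (−0.68) came inside 2-fold under scaling by total counts. The X-linked cluster from Mir322 to Mir503 held 5.11% ± 0.253, with Mir322, Mir351 (20528 ± 486 CPM), Mir542 (2266 ± 168 CPM) and Mir503 (1227 ± 425 CPM). Mir503 was higher in replicate 2 (−1.05), but lay inside 2-fold under scaling by total counts (−0.72). The cluster within Sfmbt2, known from placenta, held 0.136% ± 0.0258, with Mir467d at 684 ± 207 CPM, Mir467e at 388 ± 22.5 CPM, Mir669c at 143 ± 49.8 CPM and Mir467c at 73.2 ± 20.3 CPM. All 14 measured members of that cluster share a 20-nt stretch with another gene.

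Genes of the fibroblast, endothelial and vascular smooth muscle lists were among the most abundant, though which cells held them was not tested. The fibroblast and mesenchymal list held 10.7% ± 0.637 of the counts (SD, n = 2), led by Mir23b, Mir23a, Mir22 (14617 ± 6741 CPM) and Mir21a (12281 ± 9944 CPM). Of its 14 genes, 9 share a 20-nt stretch with another gene, Mir23b and Mir23a among them, so multi-mapped reads are missing from their counts. Mir21a (−2.21), Mir22 (−1.31) and Mir27b (−1.18) were higher in replicate 2, the other 10 tested did not differ by over 2-fold, and under scaling by total counts Mir22 (−0.98) and Mir27b (−0.84) came inside 2-fold. EdgeR's exact test, with a dispersion estimated from both libraries, did not call Mir21a, Mir22 or Mir27b. The 2 endothelial genes held 6.24% ± 1.5, nearly all of it from Mir126a, since Mir126b on the opposite strand had 4 and 3 counts. The vascular smooth muscle genes held 5.37% ± 0.939, from Mir143 and Mir145a (1488 ± 179 CPM), and Mir145b had 0 counts in both libraries. Mir126a (−0.83) and Mir143 (−0.69) did not differ by over 2-fold.

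Markers of blood cells and of other organs held few counts. The erythroid genes held 0.0797% of the counts in replicate 1 (95% Clopper-Pearson interval 0.0775 to 0.0819) and 0.0306% in replicate 2 (0.0291 to 0.0320). Mir451a (log2 ratio 1.64, 2515 and 566 counts) and Mir144 (1.56, 622 and 147 counts), which share a primary transcript, were higher in replicate 1, whereas Mir486 (0.45, 236 ± 88.5 CPM) and Mir3107 (0.30, 7.68 ± 2.37 CPM) did not differ by over 2-fold. Mir486 and Mir3107 overlap on opposite strands, and stretches shared between them were not marked. With a dispersion estimated from both libraries, edgeR's exact test called neither Mir451a nor Mir144. The leukocyte genes held 0.167% ± 0.0166, with Mir155 at 638 ± 244 CPM, Mir146 at 579 ± 137 CPM, Mir150 at 169 ± 2.31 CPM and Mir142 at 164 ± 108 CPM. Of the 7 leukocyte genes, 2 share a 20-nt stretch with another gene, Mir146 among them. Mir142, known from blood cells of many lineages, was higher in replicate 1 (1.12), and Mir223, known from myeloid cells, was higher in replicate 2 (−1.17). The latter came inside 2-fold under scaling by total counts (−0.84). The epithelial genes held 0.0629% ± 0.00477, and of the 7 tested Mir205 (−4.76, 9 and 180 counts), Mir203 (−1.69) and Mir200b (−1.45) were higher in replicate 2. The most abundant of them, Mir200c (352 ± 96.5 CPM), and Mir429 (47.7 ± 9.95 CPM) were not past 2-fold. The same edgeR test called Mir205 but not Mir203, Mir200b, Mir142 or Mir223.

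The liver gene Mir122 held 95.7 ± 13.4 CPM, or 0.00957% ± 0.00134 of the counts (SD, n = 2). The neuronal genes held 0.0458% ± 0.00978, led by Mir128-1 (230 ± 46.2 CPM), Mir338 (75.2 ± 26.6 CPM), Mir138-1 (57.6 ± 7.32 CPM) and Mir138-2 (51.1 ± 5.79 CPM). Of the 14 neuronal genes, 12 share a 20-nt stretch with another gene, Mir128-1, Mir138-1 and Mir138-2 among them, so reads that match several copies are missing from their counts. Of the 7 tested neuronal genes Mir137 was higher in replicate 1 (log2 ratio 1.69, 103 and 22 counts). The intestine and kidney genes held 0.0281% ± 0.0117, of which Mir215 (217 ± 109 CPM) was higher in replicate 2 (−1.41), while Mir194-1 (29.2 ± 0.595 CPM), Mir194-2 (18.5 ± 4.56 CPM) and Mir192 (16.4 ± 3.09 CPM) did not pass. The pluripotency clusters held 0.00600% ± 0.00144, with Mir302d at 21.8 ± 5.91 CPM, Mir302a at 13.3 ± 2.10 CPM, Mir302b at 12.1 ± 1.86 CPM and Mir293 at 4.73 ± 1.69 CPM. The endocrine and pancreatic genes held 0.00396% ± 0.00132, with Mir7-1 at 18.5 ± 5.86 CPM, Mir375 at 15.9 ± 6.44 CPM, Mir7b at 3.66 ± 1.43 CPM and Mir217 at 0.930 ± 0.433 CPM, and none of either list passed both the fold and the adjusted p. Mir217, at 4 and 7 counts, had a log2 ratio of −1.25 (exact binomial test, adjusted p = 0.347). Mir194-1 and Mir194-2, 2 of the 4 intestine and kidney genes, share a 20-nt stretch with another gene. So do 3 of the 11 pluripotency genes, Mir302a and Mir302b among them, and 2 of the 7 endocrine and pancreatic genes, Mir7-1 among them. Multi-mapped reads are missing from the counts of these genes. For every list, the number of differing genes was the same when adjusted over the list alone.

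For each list with at least 4 members that had a count in either library, the median CPM of those members was set among 10000 random lists of the same size, drawn from genes with such a count. Members at 0 counts stayed out, which left 8 of 14 Sfmbt2 genes, 10 of 14 neuronal genes and 7 of 11 pluripotency genes. The let-7 family and the Dlk1-Dio3 genes lay at percentile 100, the fibroblast list at 99.98, the miR-30 family at 99.9, the miR-15/16 family and the X-linked cluster at 99.8, and the miR-17-92 list at 97.9. Muscle genes lay at 90.8, leukocyte genes at 94.0, Sfmbt2 genes at 92.8, epithelial genes at 91.4, erythroid genes at 87.7 and neuronal genes at 85.5. The intestine and kidney genes lay at 70.0, the miR-29 family and the pluripotency clusters at 69.7, and the endocrine and pancreatic genes at 45.6. With lists and random lists limited further to genes with at least 10 counts in each library, these percentiles were 98.5 for muscle, 66.8 for Dlk1-Dio3, 69.2 for leukocyte, 54.4 for erythroid, 52.9 for Sfmbt2, 38.0 for neuronal, 30.6 for epithelial, 18.5 for intestine and kidney and 3.02 for pluripotency genes.

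**Figure D3:**
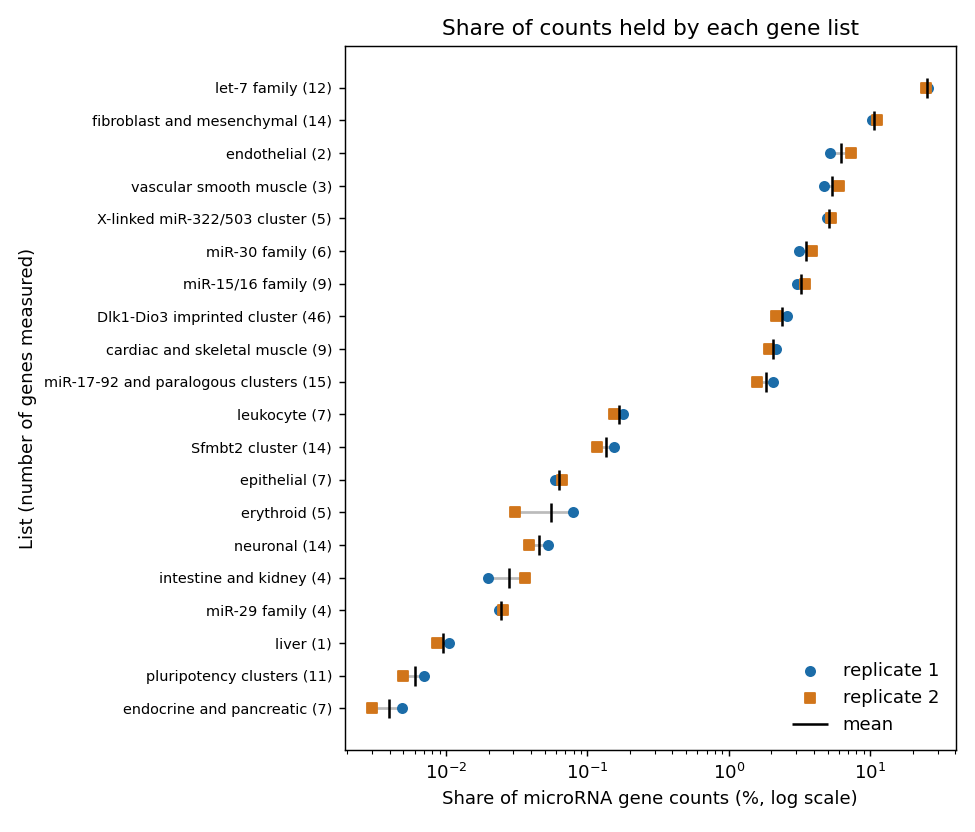
Share of microRNA gene counts, in percent on a log scale, held by each of the 20 gene lists in replicate 1 (circles) and replicate 2 (squares), with the mean as a vertical line and the number of measured genes in brackets. The let-7 family is highest at 25.1% on average and the endocrine and pancreatic genes are lowest at 0.00396%.

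Ratios within pairs of genes, which do not depend on the scaling of a library, were compared between the libraries. Mir208a made up 59.3% of the counts of Mir208a and Mir208b in replicate 1 (95% Clopper-Pearson interval 59.1 to 59.6) and 51.6% in replicate 2 (51.2 to 52.0). Mir499 made up 19.6% of the sum with Mir208a in replicate 1 and 55.4% in replicate 2, so that their order was opposite in the 2 libraries. Mir143 outnumbered Mir145a, its neighbour on chromosome 18, 33.6-fold and 36.4-fold. Mir144 held 19.8% and 20.6% of the sum with Mir451a, a difference not detectable at this depth (Fisher's exact test, two-sided, adjusted p = 0.699 over 12 pairs). Mir29a held 95.3% and 96.3% of the sum with Mir29b-1 (exact adjusted p = 0.279), against 89.8% and 79.7% of the sum with Mir29c (exact adjusted p = 1.42e-13). Mir17 held 65.4% and 67.1% of the sum with Mir92-1 (exact adjusted p = 3.12e-08). Mir486 held 43.3% and 63.5% of the sum with Mir451a (exact adjusted p = 1.26e-42), Mir195a held 1.94% and 4.24% of the sum with Mir322, and Mir126a held 99.5% and 99.9% of the sum with Mir142. Mir133b held 0.217% and 2.65% of the sum with Mir206. Mir199a-1 on chromosome 9 had 0 counts in both libraries, against 35903 and 16809 for Mir214 on chromosome 1. In both of these last pairs the first gene shares a 20-nt stretch with another gene, as do Mir29b-1, Mir29c and Mir92-1. These tests compare 2 libraries and cover counting error only.

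The libraries were alike across the abundance range, and single genes departed from it. Across the 373 detected genes, log2(CPM + 1) correlated with Pearson's r = 0.982 and Spearman's rho = 0.979 between the libraries, where genes are not independent replicates. The biological coefficient of variation was 34.0%. Of 491 genes tested, 55 differed by over 2-fold, 18 higher in replicate 1 and 37 higher in replicate 2 (two-sided exact binomial test on TMM-scaled counts, Benjamini-Hochberg adjusted). Among genes with a mean of at least 100 CPM, those higher in replicate 1 were Mir206 (log2 ratio 3.28), Mir185 (3.26, 7199 and 526 counts), Mir451a (1.64) and Mir142 (1.12). Within the same limit of 100 CPM, the 5 largest folds towards replicate 2 were those of Mir26a-2 (−3.92, 122 and 1298 counts), Mir140 (−2.41, 8455 and 31582 counts), Mir21a (−2.21, 33690 and 109355 counts), Mir31 (−2.18, 873 and 2775 counts) and Mir499 (−1.83). Mir26a-2, which lies in Ctdsp2, shares a 20-nt stretch with another gene. Among the 76 tested genes with a mean of at least 1000 CPM, 10 differed by over 2-fold.

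Scaling by total counts moved the median log2 ratio of all tested genes by 0.33. The split became 39 higher in replicate 1 and 22 higher in replicate 2, or 63.9% higher in replicate 1 against 32.7% with TMM. Genes named above as higher in replicate 1, or as not past 2-fold, are those with TMM. Under total-count scaling further genes passed 2-fold towards replicate 1, such as the abundant Mir99b (log2 ratio 1.07, against 0.74 with TMM). With a dispersion estimated from both libraries as 1 group, edgeR's exact test called 4 genes and gave 26 at an unadjusted p under 0.05. The 4 were Mir205 (adjusted p = 0.00015), Mir26a-2 (adjusted p = 0.00057), Mir206 and Mir185 (both adjusted p = 0.0055). It gave adjusted p = 0.126 for Mir140, 0.232 for Mir21a and 0.237 for Mir31.

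**Figure D4:**
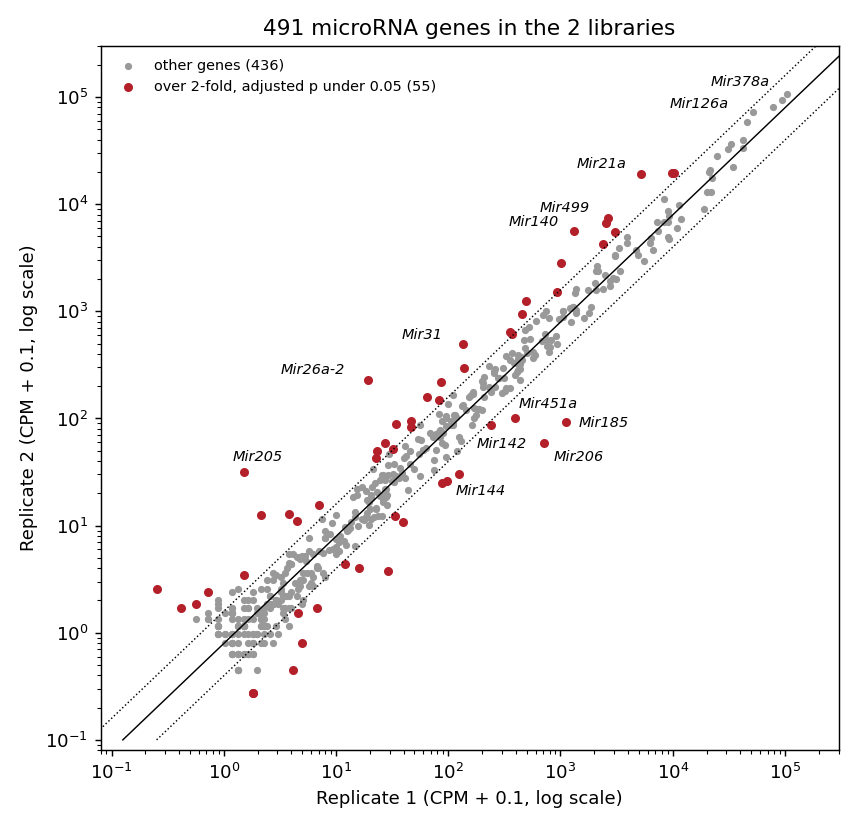
CPM + 0.1 of 491 microRNA genes in replicate 1 (horizontal, log scale) and replicate 2 (vertical, log scale), where the solid line marks equal levels after TMM scaling, the dotted lines mark 2-fold differences, and the 55 genes past both thresholds are in red. Mir206 and Mir185 lie far below the lines, and Mir26a-2 and Mir205 lie far above them.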

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

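The restriction to genes without an annotated partner on the other strand was chosen after the strand columns were seen, and no explanation of the counts below was tested. The opposite-strand column was used above only for the own-strand share and the choice of column. At the 2138 genes with no microRNA gene annotated over them on that strand, it held 134 counts in replicate 1 and 89 in replicate 2. At these genes 99.997% of the stranded counts of replicate 1 and 99.998% of those of replicate 2 were on the gene's own strand. Among them 2 genes had at least 10 opposite-strand counts in each library. Mir122 had 25 and 17, beside 675 and 488 on its own strand, and Mir203 had 14 and 12, beside 549 and 1241.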

How the results depend on the processing

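The shared stretches of 16 and 18 nt and the strand share over genes without an opposite-strand partner were chosen after seeing the data; all other alternatives were fixed earlier. With 1 count as the minimum, 638 genes were detected. The top 10 held 28.9%, a lower bound, with multi-mapped reads added to the total alone. With the 10 genes ranked anew in each setting, they held 54.6% without the most abundant gene and 55.5% to 58.5% with 1 library left out. Without a fold minimum 235 genes differed between the libraries, and edgeR's exact test called 4, since it also counts the spread between the libraries as noise. DESeq2 size factors gave 57, total-count scaling 61, no filter 56, a minimum sum of 100 counts 41 and the column without strand 48. Over all 787 genes with a count Pearson's r was 0.988 and Spearman's rho 0.931, and the cause was not tested. The column without strand has smaller totals because it drops genes such as Mir378a and Mir126a, and most list shares moved with it: muscle 2.56%, let-7 30.1%, miR-15/16 3.99%, miR-17-92 2.28%, miR-29 0.0308%, Dlk1-Dio3 2.73%, X-linked cluster 6.38%, fibroblast 13.4%, Sfmbt2 0.170%, smooth muscle 6.72%, leukocyte 0.188%, epithelial 0.0789% and liver 0.0124%. Endothelial genes came to 0.000375% and erythroid genes to 0.00763%, and Mir126a against Mir142 and Mir144 against Mir451a both came to 100%, as Mir126a, Mir142 and Mir451a have opposite-strand partners. Without Mir378a in the total, the shares were 2.29% for muscle, 28.1% for let-7, 3.64% for miR-15/16, 0.0276% for miR-29, 5.71% for the X-linked cluster, 12.0% for fibroblast, 0.186% for leukocyte and 0.0703% for epithelial genes. Genes sharing a stretch held 43.3% and 41.9% of the counts of replicates 1 and 2 at 18 nt, where Mirlet7i and Mirlet7g share too, and 52.2% and 51.9% at 16 nt. Genes without an opposite-strand partner had 99.998% of stranded counts on their own strand. Of 94 named genes, 51 moved in CPM with the column without strand and 1 with TMM library sizes. Leaving out 1 of 2 libraries gives the other's value, which decides Mir206 (58.5 or 718 CPM), Mir26a-2 (19.0 or 229 CPM) and Mir185 (92.9 or 1122 CPM). Of the lists' percentiles among random lists, 15 moved when the random lists came from detected genes alone, 12 with mean log2(CPM + 1) (pluripotency to 36.1, endocrine to 18.9) and 11 with the column without strand (erythroid to 0.005). No paired analysis was possible because there is only 1 group. Genes under 0.530 CPM are below the depth of replicate 2.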

Other observations

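Of the tests below, only that of hairpin GC content was set before its result was seen; the others, and the choice of the clusters described, came after. Neighbouring microRNA genes were often unequal in abundance. Mir191 held 7092 ± 306 CPM and Mir425, beside it on chromosome 9, 900 ± 85.5 CPM (SD, n = 2). On the X chromosome Mir532 held 2319 ± 210 CPM against 59.4 ± 7.47 CPM for Mir362 in the same cluster. Members of the cluster of Mir99b, Mirlet7e and Mir125a on chromosome 17, which lies in Spaca6, were closer together, at 14111 ± 7079, 10516 ± 1052 and 7614 ± 1091 CPM.

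Mir298 and Mir296 lie next to each other on chromosome 2 (174267047 to 174267585, minus strand, mm10), yet their log2 ratios of replicate 1 over replicate 2 went opposite ways, −1.73 for Mir298 (16412 and 38086 counts) and 0.57 for Mir296 (10355 and 4888 counts). Under scaling by total counts the ratios were −1.40 and 0.90. On chromosome 12, only genes with at least 100 counts in the sum of both libraries were taken. The 11 such genes from 109563692 to 109595388, Mir127 among them, had a median log2 ratio of 0.52 with 8 above 0. The 33 such genes from 109709060 to 109747960, Mir379 among them, had a median of −0.11 with 12 above 0. Scaling by total counts adds 0.33 to both medians and turns the sign of the second. The difference between these stretches was not tested.

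The first pattern weighed is the low count of the Mir1a and Mir133 genes. In 24 genomic clusters, genes sharing a 20-nt stretch with another gene were compared in abundance with neighbours that share none. The median log2 difference was −3.48, lower in 17 clusters. The mean difference was −2.79 (two-sided sign-flip permutation of the mean, p = 0.0022). Without the cluster of Mir133b the median was −2.85 with 16 of 23 lower. All 5 Mir1a and Mir133 genes share such a stretch, so the loss of reads that match several copies is consistent with the pattern. Assignment of their reads to the opposite strand was argued against, since the highest count there was 8. A low abundance in these hearts cannot be told apart from that loss, because 44.9% or more of the mapped reads of a library were multi-mapped and cannot be divided among genes, and no biological explanation was tested.

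The second pattern is the size of the differences between the libraries in single genes. Of the tested genes, 47.9% passed the exact binomial test at an adjusted p under 0.05, but this sets single libraries against the counting of reads, and without molecular identifiers the sampling of molecules stays open. Hairpin GC content correlated weakly with the log2 ratio (Spearman's rho 0.21 over 296 genes, permutation p = 0.00046), but 39 of 41 genes stayed over 2-fold in the same direction after a linear GC trend was removed, which argues against it as the whole cause and leaves a partial contribution open. A bias acting on each sequence on its own, such as in ligation or PCR, cannot be told apart from differences between clusters, as the intraclass correlation within clusters was 0.18 (permutation p = 0.018), 0.25 without the largest cluster (permutation p = 0.0094) and 0.23 without genes sharing a 20-nt stretch (permutation p = 0.012), all between the bounds set for either answer. Differences between the animals stay open and untested, since the labels name no condition that separates them.

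The third pattern is that Mir206 and the erythroid genes Mir451a and Mir144 were higher in replicate 1, where edgeR's exact test with an estimated dispersion called Mir206 alone of the 3. More red blood cells in that heart could account for the erythroid part but remain open because of Mir486. Its log2 ratio, the lowest of the erythroid ratios weighed, was 0.45 with TMM and 0.78 with total-count scaling. Mir486 lies in Ank1, which muscle also expresses, and stretches that it may share with the overlapping gene Mir3107 were not marked. Blood of all cell types stays open too, as its markers went both ways, with Mir142 at 1.12, Mir150 at −0.36 and Mir223 at −1.17, while ratios of single genes scattered with an SD of 0.80. Skeletal muscle in the sample of replicate 1 may have brought Mir206, but the other skeletal muscle genes had at most 190 counts in a library, too few to test. Their ratios were below 0 for Mir1a-1 (−1.55), Mir1a-2 (−0.99), Mir133a-1 (−0.77) and Mir133b (−0.37) and above 0 for Mir133a-2 (1.81, 12 and 2 counts). These ratios cover only the reads that were not multi-mapped, so skeletal muscle stays open.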
